A study of Mus musculus with 28 samples.

How the data were processed

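The samples were monocyte-derived cells from mice on the C57BL/6 background, sorted and profiled on a NanoString nCounter panel. Per the labels' protocols, monocytes of wild-type (WT) or Trem1-/- donors were transferred into CCR2-/- recipients, in which blood monocytes are scarce because CCR2 is needed for their exit from the bone marrow. The recipient's small intestine was either left alone (control) or surgically manipulated 1 day before the transfer (inflamed). At day 1 after transfer, 100 donor-derived cells per recipient were sorted from the small intestine, and their RNA was reverse-transcribed immediately. Primary bone marrow monocytes of both genotypes were profiled as well. The number of bone marrow cells per sample was not given in the sources used here. Per the labels' protocols, the cDNA was pre-amplified with multiplexed target enrichment primers and hybridised to probe pairs of a barcoded tag set, so that the values are counts of barcodes after amplification and not counts of original RNA molecules.

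The authors deposited a table of raw barcode counts per probe and a table of normalised values. The raw table named 72 targets by symbol, RefSeq transcript and target position on the transcript. Of these, 69 transcript identifiers were matched to the reference table. The probes read transcripts, so no genome build or chromosome position applied. The deposited raw values were whole counts in 14 of the 28 samples. In the other 14, the deposited values were expected counts in the sense that every gene value was a whole number times a multiplier: 1.33 in 8 samples, 1.333 in 5 and 2 in 1. Dividing by the multiplier gave whole numbers for 100.0% of the values, with a tolerance of 0.0001. In 5 of the WT intestinal samples the control probes had been multiplied too. In the remaining multiplied samples, which included all of the Trem1-/- ones, the control probes had not been. The reason for the multipliers was not given in the sources used here. The plan was to test the counts as deposited. Once the multipliers were seen they were divided out, and the counts as deposited became an alternative. In the authors' normalised table, a score without a stated unit, each sample was its raw values times 1 factor. The factors ranged from 0.407 to 3.12, and the ratio varied between genes by at most 0.036%. How the authors chose the factor was not given in the sources used here, nor was the counting software. The normalised table therefore entered only as an alternative.

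Values were present in all 28 samples for 55 targets other than housekeeping genes. Trem1 and Retnla had values only in the 10 intestinal samples with WT donors. The cells of Trem1 in every Trem1-/- and bone marrow sample were blank, so the donor genotypes could not be checked against Trem1 itself. The authors left 10 further targets blank in every sample (Ccr8, Cd163, Csf2, Cx3cl1, Flt3, Il4, Nos2, Pparg, Stat3 and Zbtb46), and these were not analysed here. Of the housekeeping genes, Actb, Gapdh and Rpl19 had values, and Gusb and Hprt were blank. Background in a sample was the mean of its 5 negative control probes plus 2 SD.

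Total gene counts per sample, multipliers divided out, ran from 720570 to 1625959 with a median of 1348258.5. The background limit ran from 16.8 to 59.0 counts with a median of 41.7. The counts follow pre-amplification without molecular identifiers, so these depths cover counting error only and the number of original molecules is unknown. The planned omission of samples with a very low housekeeping level removed 0 of 28 samples and changed nothing. No pair of samples within a group was a copy, since the lowest chi-square per degree of freedom between members of a group was 264.9.

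Each sample was scaled by the geometric mean of Actb, Gapdh and Rpl19, relative to the geometric mean of that value over all samples. Levels are given as normalised counts on this scale. Differences were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. A gene was tested when it lay above background in at least 3 samples. This kept 55 genes, or 54 in the bone marrow comparison. The comparisons among intestinal groups shared 1 fit of 22 samples, and the bone marrow comparison used 6 samples. Comparisons of intestine with bone marrow used all 28. Trem1 and Retnla were tested in a separate fit of the WT intestinal samples alone, over 56 genes. Log2 fold changes are given with the standard error (SE) of the fit, and levels with the standard deviation (SD) over mice. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for tables, exact permutation tests and figures.

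Gene lists, comparisons, tests and the rule for naming genes were fixed before the data were examined, apart from the test of Trem1 and Retnla. The plan was to test Trem1 between genotypes within each source, which the blank values prevented. Both genes were instead compared between WT inflamed and WT control cells. The 18 lists covered monocyte and macrophage functions, housekeeping genes and markers of other cell types. Lists with at least 3 tested members were tested with fry of limma 3.58.1 on log2 normalised counts plus 1, adjusted over the lists of a comparison. Fry is self-contained: it asks whether the members move, on balance, in 1 direction, and does not compare them with other genes. Metabolism and hypoxia genes had only 2 tested members, Arg1 and Vegfa, and so no fry test. No member was tested of the lists for apoptosis, the cell cycle, neutrophils, lymphocytes, eosinophils with basophils and mast cells, or epithelium with stroma and endothelium, so the panel did not measure those cell types. The rule named Trem1 first. It then named, per comparison, all genes past the threshold up to 25, or else those with the largest change (25 among intestinal groups, 12 for comparisons with bone marrow). It also named up to 4 members per list with the largest change. Genes named without having passed the threshold were chosen from these after their values were seen. Values of 2 genes of the panel are not reported here, though both were kept in the tests and counts.

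The alternatives were TMM, DESeq2 median-of-ratios, total-count and positive-control scaling, each housekeeping gene left out, no or a stricter filter on low counts, background subtraction, DESeq2 1.42.0, limma with 1 or 20 added before the logarithm, edgeR with robust estimation, the authors' normalised values, other sets of groups in the fit, each mouse left out, and the mouse number as a block. Chosen after seeing the data were the class of multiplier (none, about 4/3, or 2) as a block, samples of 1 class alone, the counts as deposited, and both blocks for the list tests. Cartridge or run was not given in the files, so it could not be a block. Nothing in the labels said that a mouse number pairs mice. In the bone marrow, the residual correlations between the WT and Trem1-/- sample of the same number ran from 0.198 to 0.794 in 3 pairs. Between intestinal groups, with 5 pairs per combination, they ran from -0.345 to 0.314 for WT control and inflamed, from -0.29 to 0.589 for Trem1-/- control and inflamed (4 of 5 over 0.1), from -0.664 to 0.228 between genotypes in control and from -0.146 to 0.561 between genotypes in inflamed intestine. They ran from 0.006 to 0.416 for Trem1-/- control with WT inflamed and from -0.288 to 0.039 for Trem1-/- inflamed with WT control.

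The test was run on simulated data for inflammation in each genotype and for genotype in inflamed intestine and in bone marrow. There were 20 panels per comparison with 200 changed genes, drawn with the spread fitted here. Genes were drawn independently and the housekeeping genes followed the scale without error. The shares recovered therefore leave out error in the scaling and may be too high. For inflamed against control WT cells, it recovered 31.2% of genes changed by 1 on the log2 scale, 76.2% of those changed by 2 and 95.0% of those changed by 3. In the bone marrow, with 3 mice per group, the shares were 6.2%, 36.2% and 70.0%.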

Results

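Monocyte-derived cells recovered from the small intestine were compared by donor genotype and by the state of the recipient's intestine, and with monocytes of the bone marrow. The 28 samples fell into 6 groups. Cells of WT donors came from 5 control and 5 inflamed recipients, cells of Trem1-/- donors from 5 control and 7 inflamed recipients, and bone marrow monocytes from 3 mice of each genotype. The total gene count per sample ran from 1095550 to 1456461 in WT control cells, from 921941 to 1567612 in WT inflamed cells, from 720570 to 1326236 in Trem1-/- control cells and from 1351956 to 1583736 in Trem1-/- inflamed cells. In bone marrow it ran from 1205501 to 1625959 for WT and from 1165758 to 1465470 for Trem1-/-. Housekeeping-normalised levels are compared throughout, with edgeR's adjusted p.

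Trem1 encodes an activating receptor of myeloid cells that amplifies inflammatory signalling. Among cells of WT donors, Trem1 (transcript NM_021406.5, target positions 1705 to 1804) was higher in the inflamed intestine, at 5117 ± 2022 normalised counts (SD, n = 5) against 1240 ± 1149 (n = 5) in controls (755.9 without WT control mouse 3). The log2 fold change was 2.04 (SE 0.65, adjusted p = 0.0289 over 56 genes), and 4 of 5 inflamed samples lay above every control. A two-sided exact permutation test of the mean log2 levels gave p = 0.0159, where 252 arrangements allow 0.0079 at the smallest. The edgeR call ended when WT control mouse 1, 2 or 4 or WT inflamed mouse 1 or 5 was left out, with log2 fold changes of 1.91, 1.87, 2.08, 1.94 and 1.95. Trem1 was blank in the other groups, so its level in Trem1-/- cells was not analysed here. The comparison within WT cells took the place of the planned one between genotypes.

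How WT cells responded to the inflamed intestine was the first question. Inflammatory cytokines rose as a group, with 5 of 5 tested members higher (fry adjusted p = 7.73e-08), a call kept under every alternative run for the lists. Il1a, an alarmin-type cytokine, went from 8877 ± 2519 to 148894 ± 18035 normalised counts (SD, n = 5 each; log2 fold change 4.07, SE 0.43, adjusted p = 7.63e-08). Il6, an acute-phase cytokine, rose by 5.12 (SE 0.86, adjusted p = 3.76e-05) on the log2 scale. Il23a, the p19 chain of interleukin 23, rose by 4.78 (SE 0.75, adjusted p = 2.22e-05). WT control counts lay near the background limits of 26.3 to 46.7, at 32 to 82 for Il6 and 54 to 160 for Il23a. The sizes of both changes are therefore uncertain. Tnf rose by 2.08 and Il1b by 1.30.

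Among 8 chemokines, 3 rose, 2 fell and 3 did not pass (fry up, adjusted p = 3.06e-05). The list's mean was 0.64 and its median -0.35, so that the median ran against the test, and 3 members rose and 3 fell when adjusted over the list alone. Ccl7, which attracts monocytes, showed the largest change in this comparison, from 161 ± 159 (90.2 without WT control mouse 5) to 20862 ± 10928 normalised counts (log2 fold change 7.02, SE 0.67, adjusted p = 3.95e-08). Cxcl1, an attractant of neutrophils, rose by 3.90, and Ccl2, the main ligand of CCR2, by 2.80. Of 3 interferon-induced chemokines, Cxcl10 did not pass and 2 went the other way: Cxcl9 had a log2 fold change of -4.57 (SE 1.16, adjusted p = 0.0026) and Cxcl11 of -2.28 (SE 0.84, adjusted p = 0.0292). Cxcl11 lost its call in 11 of 32 alternatives, among them the omission of WT control mouse 2 or of WT inflamed mouse 2, 3, 4 or 5.

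Interferon response genes fell as a list (fry adjusted p = 0.00104), with 3 of 5 lower and 2 not past the threshold. Chemokine receptors and adhesion genes also fell, with 4 of 8 lower and 4 not past (fry adjusted p = 0.00104). Cx3cr1, the fractalkine receptor of tissue macrophages and patrolling monocytes, had a log2 fold change of -3.70 (SE 0.74, adjusted p = 0.000308), and Ccr2, the receptor by which monocytes leave the marrow, of -1.73 (SE 0.51, adjusted p = 0.0078). WT inflamed counts of Cx3cr1 lay at 42 to 214, against background limits of 16.8 to 40.1, so the size of its change is uncertain. Itgax (CD11c) had a log2 fold change of -2.38 and Itgb7, an integrin chain of gut homing, of -1.16. With positive-control scaling neither list passed, at adjusted p = 0.0729 and 0.327.

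Dendritic cell markers Itgax and Irf4 fell while Ccr7 did not pass (fry adjusted p = 0.00156). Of 8 transcription factors of monocyte differentiation, 2 fell, Irf4 among them, and 6 did not pass (fry adjusted p = 0.00305). Both lists lost the call with positive-control scaling, at adjusted p = 0.222 and 0.649, and the transcription factors also without Rpl19, at 0.0629. Of 14 macrophage maturation genes, 1 rose, 4 fell and 9 did not pass (fry down, adjusted p = 0.107; 0.000849 for change in either direction). This list passed downwards in 5 of 12 alternatives, with TMM (adjusted p = 0.00304), DESeq2 (0.00914) and total-count scaling (0.0213), without Actb (0.0364) and with the multiplier class as a block (0.0194). Il10, an anti-inflammatory cytokine, rose from 3588 ± 1535 to 14943 ± 3641 normalised counts, a log2 fold change of 2.06 (SE 0.30, adjusted p = 7.6e-06). H2-Ab1, a chain of MHC class II, had a log2 fold change of -2.08 (SE 0.72, adjusted p = 0.0211), and Csf1r, the receptor of macrophage colony-stimulating factor, of -1.10. The call of Csf1r ended without WT control mouse 3, and those of H2-Ab1 and Csf1r with positive-control scaling.

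Of 8 alternative activation genes, 2 rose (Arg1 and Il10), 2 fell (Irf4 and Tgfb1) and 4 did not pass (fry up, adjusted p = 0.0348), but the call was kept in 7 of 12 alternatives and the direction turned with TMM scaling (adjusted p = 0.783). Arg1, which breaks down arginine, had a log2 fold change of 6.12 (SE 1.09, adjusted p = 7.35e-05), with a wide spread between mice at 86588 ± 110831 against 1243 ± 1951 normalised counts. Without WT control mouse 5, at 4723, the control mean was 372.5 and the log2 fold change 7.86, and without WT inflamed mouse 3, at 250855, the inflamed mean was 45521 and the log2 fold change 5.20. Unscaled samples alone gave 2.63 and those multiplied by about 4/3 alone 9.62, both past the threshold. Of 11 pattern recognition and TREM signalling genes, 3 rose (Cd14, Cd80 and Tlr4), 1 fell (Card9) and 7 did not pass (fry up, adjusted p = 0.0437), a call kept in 3 of 12 alternatives, and this direction too turned with TMM scaling (adjusted p = 0.283). With the multiplier class as a block the adjusted p of that list was 0.16, and with the mouse number as a block 0.116. Cd80, a costimulatory ligand for T cells, rose by 1.71 on the log2 scale (SE 0.28, adjusted p = 3.76e-05), and Cd14 and Tlr4, parts of the lipopolysaccharide receptor, by 1.00 and 1.11. The calls of Cd14 and Tlr4 ended with TMM scaling. Of the 4 Ly6C-high monocyte genes, Ccr2 fell and 3 did not pass (fry down, adjusted p = 0.343, where the list's median of 0.20 has the opposite sign), and this list passed in 1 of 12 alternatives, with TMM scaling (0.0384).

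In total, 26 of 55 genes passed the threshold in WT cells, 14 higher and 12 lower. Of the 55 tested, 19 had groups without overlap, where chance gives 0.79%, and all 19 had passed. The balance of directions depended on the scaling: 11 higher and 18 lower with TMM, 12 and 16 with total counts, 14 and 3 with positive controls, and 16 and 6 in the authors' normalised values.

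**Figure D1:**
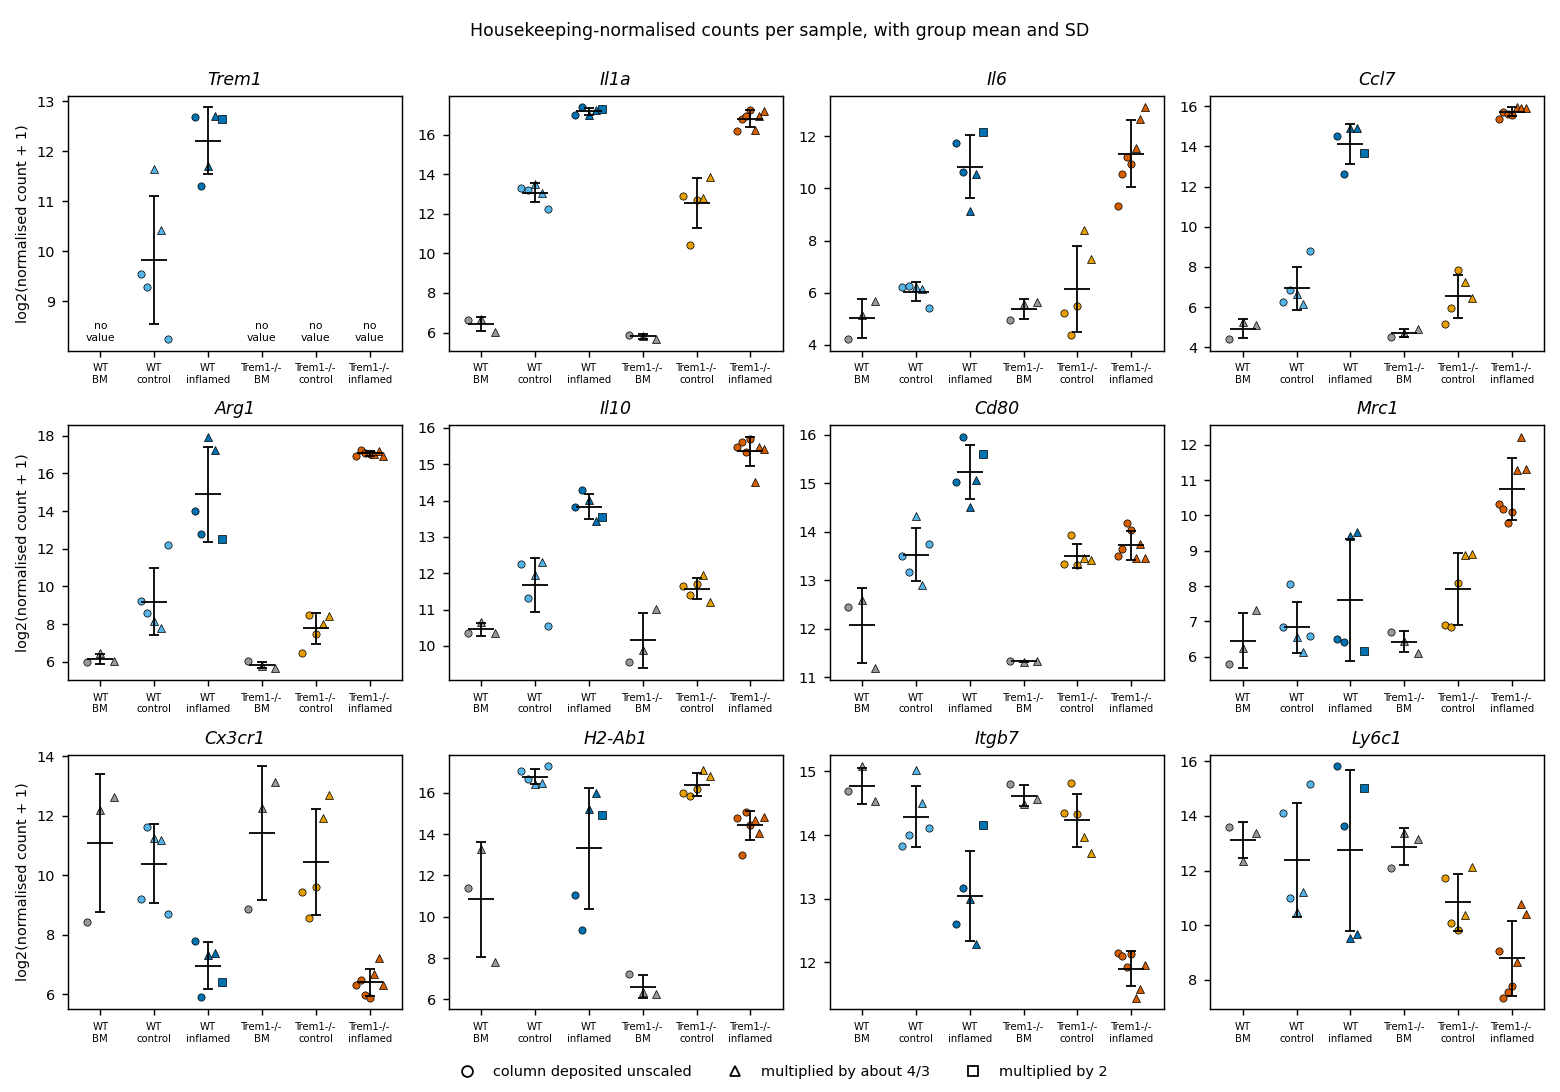
Log2 normalised counts plus 1 (y axes) of 12 genes in each of 6 groups (x axes), where each point is a sample, its shape gives the multiplier class, and bars give the group's mean and SD on the log2 scale. Il10 lay at 14.51 or above in all 7 Trem1-/- inflamed samples, above every WT inflamed sample, and Cd80 at 14.18 or below, under every WT inflamed sample.

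The same question was asked of Trem1-/- cells. Again inflammatory cytokines were higher in the inflamed intestine, with 4 of 5 past the threshold and Il1b not past it at a log2 fold change of 0.63 (adjusted p = 0.156). Il1b passed in 4 of 34 alternatives, among them DESeq2 scaling and the omission of Trem1-/- control mouse 4 (0.97), and without Trem1-/- control mouse 2 it was at 0.40. The list passed with fry adjusted p = 8.78e-09. Il23a rose by 5.63 (SE 0.77), Il6 by 4.90 (SE 0.83) and Il1a by 3.97 (SE 0.42) on the log2 scale. In Trem1-/- control cells Il6 lay above background in 4 of 5 samples. Tnf rose by 1.36 (adjusted p = 0.02), a call that ended without Trem1-/- control mouse 5 and with TMM, DESeq2 or total-count scaling.

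Among chemokines, 4 of 8 rose, 1 fell and 3 did not pass (fry adjusted p = 8.78e-09). Ccl7 went from 113 ± 78.2 (SD, n = 5) to 54747 ± 7921 normalised counts (n = 7), a log2 fold change of 8.92 (SE 0.72, adjusted p = 6.6e-10). Cxcl1 rose by 5.47 (SE 0.42) and Ccl2 by 3.69 (SE 0.30). Cxcl10, an interferon-induced chemokine, rose by 1.71 (SE 0.61, adjusted p = 0.0234), a call that ended without Trem1-/- control mouse 1 or 2 and with the multiplier class as a block. Cxcl9 fell, with a log2 fold change of -3.30 (SE 0.95).

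Alternative activation genes passed as a list (fry up, adjusted p = 1.96e-05), with 3 of 8 higher, 2 lower and 3 not past. Arg1 rose from 246 ± 114 to 137110 ± 11267 normalised counts, the largest change in this comparison at a log2 fold change of 9.12 (SE 1.23, adjusted p = 1.94e-06). Mrc1, the mannose receptor of macrophages, rose from 290.2 ± 179.6 to 2033 ± 1392 (log2 fold change 2.81, SE 0.70, adjusted p = 0.00263). Il10 rose from 3108 ± 609 to 43277 ± 9625, a log2 fold change of 3.80 (SE 0.31, adjusted p = 6.6e-10). All 3 kept their calls under the 34 alternatives.

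Chemokine receptors and adhesion genes fell, with 5 of 8 lower and 3 not past (fry adjusted p = 1.86e-05; 0.255 with positive-control scaling). Cx3cr1 had a log2 fold change of -4.82 (SE 0.68) and Itgb7 of -2.36 (SE 0.29). Trem1-/- inflamed counts of Cx3cr1 lay at 58 to 147, against background limits of 39.4 to 53.2, so the size of its change is uncertain. Transcription factors fell in 4 of 8 cases (fry adjusted p = 0.000782), a direction that turned with positive-control scaling (adjusted p = 0.922), and dendritic cell markers in 3 of 3 (fry adjusted p = 0.000973; 0.376 with positive-control scaling). Spi1, the factor PU.1 of the myeloid lineage, had a log2 fold change of -0.72, with 0.20 for Spi1 in the authors' normalised values. Macrophage maturation genes moved both ways, with 2 higher (Il10 and Mrc1), 6 lower and 6 not past. Their fry adjusted p was 1.15e-10 for change in either direction and 0.736 for 1 direction, where the test pointed up while the median was -0.14 and the mean -0.26. H2-Ab1 had a log2 fold change of -1.94 (SE 0.64), which lost its call with limma, positive-control scaling and the authors' normalised values.

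The remaining lists did not pass with housekeeping scaling, though some did under alternatives. Of the interferon response genes, 1 rose (Cxcl10), 2 fell, Cxcl9 among them, and 2 did not pass (fry down, adjusted p = 0.134), with the list past the threshold downwards in 4 of 12 alternatives: TMM (0.0149), DESeq2 (0.0215) and total-count scaling (0.00843), and without Actb (0.035). Of the pattern recognition genes, Cd14 rose, Card9 and Nfkb1 fell and 8 did not pass (fry up, adjusted p = 0.4995), and the list passed downwards with total counts (0.011) and upwards without Rpl19 (0.0287). Of the 4 Ly6C-high monocyte genes, Ccr2 fell over all genes and none passed when adjusted over the list alone (fry down, adjusted p = 0.0968). The list passed downwards in 4 of 12 alternatives, with TMM (0.0178) and total-count scaling (0.00146), without Actb (0.0104) and with the mouse number as a block (0.0126).

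In Trem1-/- cells, 27 of 55 genes passed, 12 higher and 15 lower. There was no overlap between groups for 17 of the 55 tested, where chance gives 0.25%, and 15 of these had passed. Total-count scaling gave 9 higher and 21 lower, positive controls 15 and 4, and the authors' normalised values 18 and 2. Across the 55 genes, the log2 fold changes of both genotypes, which shared no sample, had a Pearson r of 0.906 and a Spearman rho of 0.775, although genes are not independent replicates. Of the genes that passed, 10 were higher in both genotypes, where 3.1 would be shared by chance, 11 were lower in both, where 3.3 would be, and none (0) went in opposite directions.

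**Figure D2:**
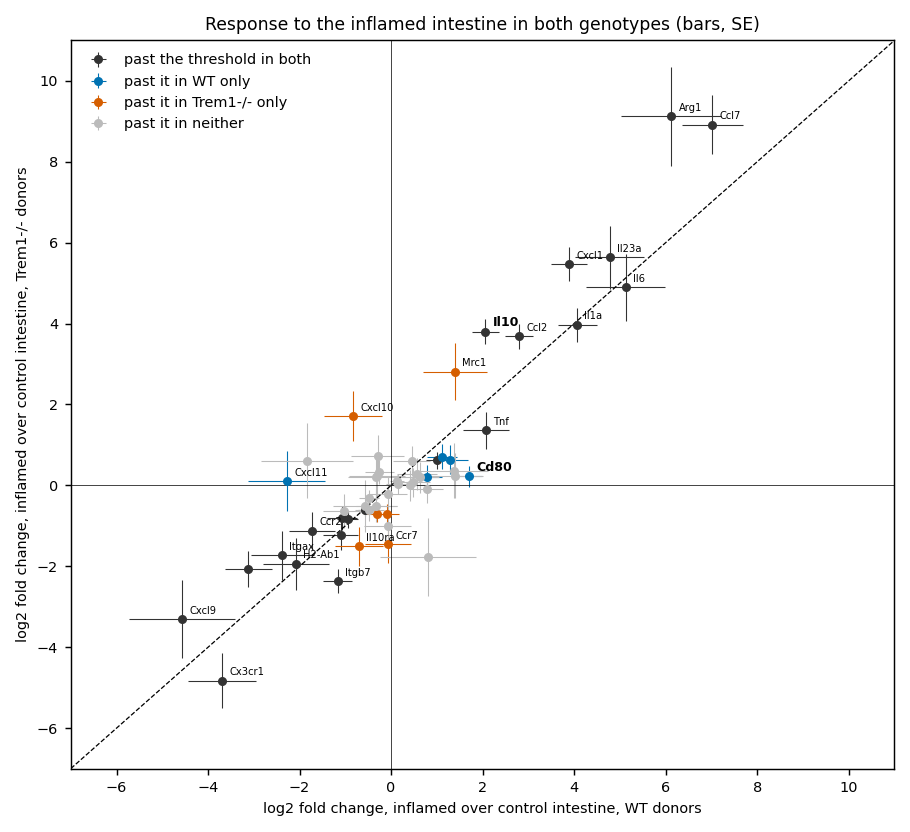
Log2 fold change of each of 55 genes between inflamed and control intestine, in WT donors on the x axis and Trem1-/- donors on the y axis, with bars for the SE and a dashed line where both are equal. Il10 lies above the line at 2.06 and 3.80, and Cd80 below it at 1.71 and 0.23.

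Whether the response differed between genotypes was tested as an interaction, and 2 of 55 genes passed. Il10 rose more in Trem1-/- cells, by a further 1.74 on the log2 scale (SE 0.39, adjusted p = 0.013). Controls had 3588 ± 1535 (WT) and 3108 ± 609 (Trem1-/-) normalised counts of Il10, and inflamed samples 14943 ± 3641 (n = 5) and 43277 ± 9625 (n = 7). The response of Cd80 was smaller, with an interaction of -1.48 (SE 0.38, adjusted p = 0.0213): it went from 12535 ± 5073 to 40888 ± 15837 in WT cells and from 11712 ± 2280 to 13700 ± 2926 in Trem1-/- cells, where the log2 fold change was 0.23 (adjusted p = 0.55; past the threshold in 2 of 34 alternatives, positive-control scaling and the authors' normalised values). The other members of both lists to which Il10 belongs did not pass, and neither did the 10 other pattern recognition genes.

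Chemokines passed as a list in the interaction (fry up, adjusted p = 0.0418), although none (0) of the 8 members passed over all genes and 3 were higher when adjusted over the list alone. Cxcl1 had an interaction of 1.57 (SE 0.48, adjusted p = 0.0704), Ccl7 of 1.90 (adjusted p = 0.138) and Cxcl10 of 2.54 (adjusted p = 0.114). They passed in 9, 0 and 5 of 43 alternatives. Cxcl1 passed with DESeq2 and limma, with the multiplier class as a block (1.51), within unscaled samples and without WT control mouse 1 (1.70) or 5 (1.70), WT inflamed mouse 3 (1.86) or Trem1-/- inflamed mouse 5 (1.67). Cxcl10 passed with DESeq2, TMM scaling, within unscaled samples and without WT control mouse 4 (2.81) or Trem1-/- inflamed mouse 5 (2.73). Ccl7 was at 1.07 without WT control mouse 5. The list kept its call in 6 of 12 alternatives. With the mouse number as a block its adjusted p was 0.161 and with the multiplier class as a block 0.0693. The other 9 lists tested had fry adjusted p of 0.144 or more and passed in 0 of 12 alternatives. The target of Il10 spans positions 986 to 1085 of NM_010548.1 and that of Cd80 positions 211 to 310 of NM_009855.2.

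The interaction of Il10 kept its call in 39 of 43 alternatives and ended with DESeq2 scaling, with the authors' normalised values and within either multiplier class alone (1.41, adjusted p = 0.0771, and 1.94, adjusted p = 0.117). That of Cd80 kept it in 33 of 43 and ended, among others, with TMM scaling, with the mouse number as a block (-1.42, adjusted p = 0.103) and without WT control mouse 2, WT inflamed mouse 2 or 5, or Trem1-/- control mouse 2.

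Cells of both genotypes were then compared within the inflamed intestine. There, as in control intestine, positive-control means did not overlap between genotypes (at most 729.3 in WT and at least 766.2 in Trem1-/- intestinal samples). A run effect therefore cannot be told from a genotype difference in either state of the intestine. Ly6c1, a surface marker of classical monocytes, was lower in Trem1-/- cells at 660.0 ± 637 (SD, n = 7) against 21070 ± 24462 normalised counts (n = 5; 11870 without WT inflamed mouse 1), a log2 fold change of -5.0 (SE 1.06, adjusted p = 0.00108). Samples deposited without a multiplier gave -7.01 (SE 1.06) and those multiplied by about 4/3 gave 0.58 (SE 0.70), each with 2 WT inflamed samples. WT inflamed mouse 5, multiplied by 2, was in neither of these fits and had a log2 level of 15.02, where Trem1-/- inflamed samples averaged 8.80. The probe target, positions 237 to 336 of NM_010741.2, was not checked against the closely related gene Ly6c2. Cd80 had a log2 fold change of -1.58 (SE 0.26, adjusted p = 0.000101) and was the 1 of 18 called genes that kept its call under every alternative.

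Pattern recognition and TREM signalling genes were lower as a list, with 6 of 11 past the threshold and 5 not (fry adjusted p = 6.28e-05). Nfkb1, a subunit of NF-kappaB, had a log2 fold change of -1.39 (SE 0.25), Nod2, a sensor of bacterial cell wall fragments, of -1.38 (SE 0.33), Nfkb2 of -1.22 and Tlr4 of -1.25 (SE 0.30). Tlr4, like Ly6c1, was not lower among samples multiplied by about 4/3, at 0.15 (SE 0.28). Traf6, an adaptor of Toll-like receptor signalling, had -1.17. Tlr2 passed at -0.99, with 66.8 against 132.5 normalised counts, and lost its call in 22 of 34 alternatives. Of 8 transcription factors, 3 were lower (Spi1, Nfkb1 and Irf5) and 5 did not pass (fry adjusted p = 0.000176), with Spi1 at -1.39 (SE 0.20, adjusted p = 3.17e-05). With TMM scaling neither list passed, at adjusted p = 0.299 and 0.957, and the transcription factors did not pass with DESeq2 scaling, at 0.12.

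Il10 was higher in Trem1-/- cells, with a log2 fold change of 1.53 (SE 0.28, adjusted p = 0.000228), and so was Mrc1, at 2033 ± 1392 against 334 ± 346 normalised counts (log2 fold change 2.61, SE 0.70, adjusted p = 0.00493). Of 8 chemokines, 3 were higher and 5 did not pass (fry adjusted p = 0.0495): Cxcl1 at 1.30 (SE 0.34), Ccl7 at 1.39 (SE 0.50) and Ccl2 at 0.92 (SE 0.27). This list kept its call in 6 of 12 alternatives, and its direction turned with positive-control scaling (adjusted p = 0.584). Its adjusted p was 0.121 with the mouse number as a block and 0.0936 with the multiplier class as a block. Ccl7 lost its call without WT inflamed mouse 1, 2 or 5 or Trem1-/- inflamed mouse 6.

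Ly6C-high monocyte genes were lower as a list, with 2 of 4 past the threshold, Ly6c1 among them, and 2 not (fry adjusted p = 0.0459). This call was kept in 7 of 12 alternatives and lost with TMM (adjusted p = 0.957), DESeq2 (0.687) and total-count scaling (0.136), without Gapdh (0.116) and with the multiplier class as a block (0.14). Chemokine receptors and adhesion genes had 2 lower members, Itgb7 among them, and 6 not past (fry adjusted p = 0.0459). This call was lost under the same 5 alternatives, at adjusted p = 0.717, 0.687, 0.163, 0.129 and 0.0767, and the list's direction turned with TMM scaling. Of 14 macrophage maturation genes, Il10 and Mrc1 were higher, Csf1r (-1.33, SE 0.35) and Spi1 were lower, and 10 did not pass (fry adjusted p = 0.447; 0.00255 for change in either direction), and the list passed upwards with TMM (0.0177) and DESeq2 scaling (0.0126). Alternative activation genes had 2 higher members and 6 not past (fry up, adjusted p = 0.0852, median -0.16). This list passed upwards in 4 of 12 alternatives, with TMM (0.000235), DESeq2 (0.000539) and total-count scaling (0.0161) and without Gapdh (0.0192). Arg1 was at 0.66 (adjusted p = 0.524), and ranged over the alternatives from -0.57 to 3.55, with 3 of 34 past the threshold, by limma (2.17 at the highest) and within unscaled samples (3.55). Without WT inflamed mouse 1, 2, 3 or 5 Arg1 was at 0.40, 0.36, 1.59 or 0.36. With housekeeping scaling over all samples, edgeR called none (0) of the 5 cytokines (fry up, adjusted p = 0.66; 0.0472 with TMM scaling). Il1b was at -0.89 (adjusted p = 0.0539) and passed in 7 of 34 alternatives, among them the omission of Trem1-/- inflamed mouse 7 (-0.96). Il23a was at 1.48 (adjusted p = 0.0713) and passed in 11 of 34, among them TMM, DESeq2 and total-count scaling, both limma fits, the mouse number as a block (1.71) and the omission of WT inflamed mouse 4 (2.59) or Trem1-/- inflamed mouse 5 (1.63). Interferon response genes had 1 lower member, Irf5, and 4 not past (fry down, adjusted p = 0.929, where the mean of 0.27 has the opposite sign), and the 3 dendritic cell markers did not pass (fry down, adjusted p = 0.147; 0.0166 with positive-control scaling).

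In all, 18 of 55 genes differed between genotypes in the inflamed intestine, 5 higher and 13 lower in Trem1-/- cells. Groups did not overlap for 11 of the 55 tested, where chance gives 0.25%, and 10 of these had passed. The split was 7 higher and 2 lower with TMM, 8 and 7 with DESeq2 scaling, 0 and 29 with positive controls and 2 and 11 in the authors' normalised values.

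**Figure D3:**
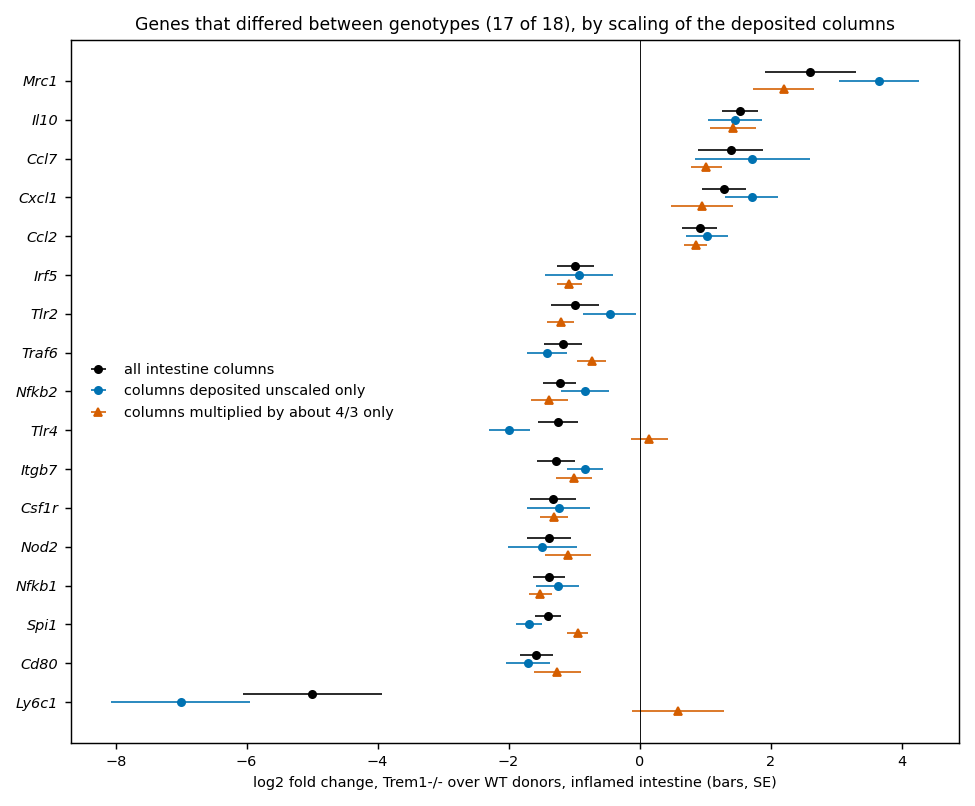
Log2 fold change of Trem1-/- over WT cells in the inflamed intestine for 17 of the 18 genes past the threshold, over all samples and within samples deposited unscaled or multiplied by about 4/3, with bars for the SE. Ly6c1 lies at -7.01 in the unscaled samples and at 0.58 in those multiplied by about 4/3, and Tlr4 at -1.99 and 0.15.

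In the control intestine, 2 of 55 genes differed between genotypes, both lower in Trem1-/- cells. Spi1 (NM_011355.1, positions 172 to 271) had 44935 ± 11532 against 89324 ± 9219 normalised counts (SD, n = 5 each; log2 fold change -0.99, SE 0.22, adjusted p = 0.00932). Nfkb2, a subunit of the non-canonical NF-kappaB pathway, had 6453 ± 1530 against 13813 ± 6072 (log2 fold change -1.10, SE 0.28, adjusted p = 0.0207). Cxcl11 did not pass, at -2.46 (adjusted p = 0.0796), but did in 5 of 32 alternatives, among them DESeq2 and the omission of Trem1-/- control mouse 5 (-2.95). Of the 55 tested, 4 had groups without overlap, where chance gives 0.79%, and 1 of these had passed.

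As lists, transcription factors (fry adjusted p = 0.00235), pattern recognition genes (0.00522) and interferon response genes (0.0337) were lower in Trem1-/- control cells. They had 1 of 8, 1 of 11 and 0 of 5 members past the threshold, against 5, 3 and 3 when adjusted over the list alone. They kept their calls in 9, 9 and 7 of 12 alternatives. With TMM, DESeq2 or total-count scaling none of the 3 passed (with TMM, adjusted p = 0.609, 0.556 and 0.461), and the interferon genes had 0.105 with the mouse number as a block and 0.0578 with the multiplier class as a block. The other 7 lists tested had fry adjusted p of 0.116 or more, and all but the cytokines passed downwards with positive-control scaling. Nfkb2 lost its call without WT control mouse 2 or 3 or Trem1-/- control mouse 2, 3 or 4. Spi1 lost it with TMM, DESeq2 and total-count scaling, as did Nfkb2.

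Bone marrow monocytes of both genotypes were compared as cells that had not been transferred. With 3 mice per group, edgeR called 0 of 54 genes, with 3 genes at an unadjusted p under 0.05, while DESeq2 called 2 and limma 0. Given as values, the 2 genes with the smallest p were H2-Ab1 at 103 ± 42.4 in Trem1-/- against 4298 ± 5066 normalised counts in WT (1461 without WT mouse 2; log2 fold change -5.38, SE 1.32, adjusted p = 0.144) and Cxcl10 (log2 fold change -3.56, adjusted p = 0.367; -0.40 without WT mouse 2). H2-Ab1 passed in 7 of 26 alternatives, among them DESeq2 and the omission of WT mouse 1 (-5.63) or 3 (-5.94) or Trem1-/- mouse 1 (-5.78), and Cxcl10 in 3, among them DESeq2 and the omission of WT mouse 1 (-4.08). Groups did not overlap for 4 of 54 genes, where chance gives 10%. The 10 lists tested had fry adjusted p of 0.737 or more and passed in 0 of 12 alternatives. With the 6 groups fitted together 1 gene passed.

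What set cells in the intestine apart from bone marrow monocytes was asked for each genotype and state. In WT control intestine, Il1a was higher by 6.67 (SE 0.58), Il1b by 4.79 and H2-Ab1 by 4.75 on the log2 scale than in WT bone marrow. These calls held under all 29 alternatives. WT bone marrow counts of Il1a lay at 75 to 153, against background limits of 34.2 to 54.0, so the size of its change is uncertain. Itgax was higher by 7.5 (SE 1.07), but in bone marrow, at a mean of 29.3 normalised counts, it lay above its sample's background limit in 1 of 3 samples. Inflammatory cytokines (2 of 5 higher, 3 not past; fry adjusted p = 6.88e-08), chemokines (4 of 8 higher, 4 not past; 0.000145) and dendritic cell markers (1 of 3 higher, 2 not past; 2.15e-05) were higher as lists, and Ly6C-high monocyte genes lower (2 of 4, Chil3 among them; 0.00348). These 4 lists kept direction and call under every alternative run for them. Macrophage maturation genes (4 of 14 higher; fry adjusted p = 0.00777), interferon response genes (1 of 5 higher; 0.00667), alternative activation genes (4 of 8 higher, 1 lower; 0.0187) and pattern recognition genes (4 of 11 higher; 0.00348) passed, but not with TMM scaling, at adjusted p = 0.0973, 0.0847, 0.513 and 0.513. They kept their calls in 8, 9, 7 and 7 of 12 alternatives. The direction of the alternative activation genes turned with TMM and DESeq2 scaling, and that of the pattern recognition genes with DESeq2 scaling. Transcription factors did not pass, but did downwards with DESeq2 scaling (fry adjusted p = 0.000414). Chemokine receptors and adhesion genes passed only upwards with the mouse number (0.0457) or the multiplier class (0.0189) as a block. In total 19 of 55 genes passed, 17 higher and 2 lower, against 11 and 5 with TMM, 10 and 12 with DESeq2 scaling, 11 and 4 with total counts and 6 and 2 in the authors' normalised values. Without WT bone marrow mouse 1 or 3, 12 genes passed. There was no overlap between groups for 12 of the 55 tested, where chance gives 3.57%, and 11 of these had passed.

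In WT inflamed intestine, all 5 inflammatory cytokines were higher than in WT bone marrow (fry adjusted p = 4.15e-14), with Il1a at 10.74, Il1b at 6.09 and Il23a at 5.03 on the log2 scale. Arg1 was higher by 10.25 and Cd14 by 3.68. WT bone marrow counts lay at 75 to 153 for Il1a, 75 to 102 for Arg1 and 69 to 126 for Il23a. The background limits there were 34.2 to 54.0, so the sizes of these changes are uncertain. Ccl7 (9.42) and Il6 (6.09) had bone marrow means of 30.4 and 34.1 normalised counts, and lay above background there in 0 and 1 of 3 samples. Chemokines were higher in 3 of 8 cases (fry adjusted p = 8.29e-09), and Ly6C-high monocyte genes lower in 2 of 4, with Ccr2 at -2.10 (0.000285). Alternative activation (0.000227), pattern recognition (5.38e-05) and dendritic cell lists (0.019) passed upwards but not with TMM scaling, at adjusted p = 0.702, 0.189 and 0.569. They kept their calls in 9, 10 and 8 of 12 alternatives. The pattern recognition list turned direction with DESeq2 scaling. Chemokine receptors and adhesion genes (fry down, adjusted p = 0.0916) and transcription factors (fry down, 0.235) did not pass. They passed downwards in 5 and 3 of 12 alternatives, TMM, DESeq2 and total-count scaling among them. Interferon response genes did not pass either, but did downwards with TMM (fry adjusted p = 0.0231) and DESeq2 scaling (0.000568). Macrophage maturation genes passed only with the multiplier class as a block, upwards (0.0306). Cx3cr1 was lower at -4.78, a size that is uncertain because its inflamed counts lay near background. Of 55 genes 27 passed, 20 higher and 7 lower, against 16 and 16 with TMM, 15 and 20 with DESeq2 scaling and 18 and 14 with total counts. Groups did not overlap for 23 of the 55 tested, where chance gives 3.57%, and all 23 had passed.

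In Trem1-/- control intestine, H2-Ab1 was higher than in Trem1-/- bone marrow by 9.79, Il1a by 7.09, Il1b by 5.11, Cxcl10 by 4.51 and Cd14 by 3.35 on the log2 scale. These calls held under all 29 alternatives. Bone marrow counts lay at 107 to 248 for H2-Ab1 and 70 to 96 for Il1a, against background limits of 44.4 to 59.0. The sizes of these 2 changes are therefore uncertain. Inflammatory cytokines were higher in 3 of 5 cases (fry adjusted p = 1.25e-08), chemokines in 4 of 8 (0.00107; 0.817 with positive-control scaling and 0.0576 with the mouse number as a block) and dendritic cell markers in 2 of 3 (1.76e-05; 0.0797 with positive-control scaling). Ly6C-high monocyte genes were lower in 2 of 4 (0.00107). Macrophage maturation (0.00926), alternative activation (0.0022) and pattern recognition lists (0.00926) passed upwards, but not with TMM scaling, at adjusted p = 0.0878, 0.481 and 0.787. They kept their calls in 7, 8 and 6 of 12 alternatives. Positive-control scaling turned the direction of the alternative activation and pattern recognition lists, and DESeq2 scaling that of the latter. Transcription factors (fry adjusted p = 0.000724) and chemokine receptors with adhesion genes (0.0496) passed only with DESeq2 scaling, downwards. Interferon response genes passed only upwards without Actb (0.0336), without Gapdh (0.0347) or with the multiplier class as a block (0.0434). Of 55 genes 19 passed, 17 higher and 2 lower. Of the 55 tested, 21 had groups without overlap, where chance gives 3.57%, and 18 of these had passed. The split was 14 and 6 with TMM, 13 and 11 with DESeq2 scaling, 15 and 4 with total counts, 8 and 8 with positive controls and 6 and 22 in the authors' normalised values.

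In Trem1-/- inflamed intestine, Arg1 was higher than in Trem1-/- bone marrow by 11.24, Il1a by 11.06 and Il10 by 5.11, and Mrc1 by 4.56 on the log2 scale. Bone marrow counts lay at 71 to 106 for Arg1, 70 to 96 for Il1a and 96 to 170 for Mrc1. The background limits there were 44.4 to 59.0, so the sizes of these 3 changes are uncertain. All 5 inflammatory cytokines were higher (fry adjusted p = 3.36e-15), as were 4 of 8 chemokines (3.27e-11) and 4 of 8 alternative activation genes, with 2 lower (1e-08). All 4 Ly6C-high monocyte genes were lower (4.43e-06), with Ly6c1 at -3.61, Ccr2 at -1.37 and Chil3 at -1.08, the last 2 of which lost their calls when a Trem1-/- bone marrow mouse was left out (mouse 3 for Ccr2, 1 or 2 for Chil3). Chemokine receptors and adhesion genes were lower in 4 of 8 cases, with 1 higher (0.00109). Cx3cr1 was at -5.76, a size that is uncertain because its inflamed counts lay near background. Macrophage maturation (6 of 14 higher, 1 lower; 0.00186), pattern recognition (4 of 11 higher, 3 lower; 0.00175) and dendritic cell lists (1 of 3 higher; 0.00291) passed upwards, but not with TMM scaling, at adjusted p = 0.0692, 0.946 and 0.128. Each kept its call in 8 of 12 alternatives. The pattern recognition list turned direction with DESeq2 and total-count scaling. Transcription factors were lower in 3 of 8 cases (fry adjusted p = 0.0219). Their adjusted p was 0.194 with the mouse number as a block, 0.129 without Gapdh and 0.0537 with positive-control scaling. Interferon response genes passed only with DESeq2 scaling, downwards (fry adjusted p = 0.0366). Of 55 genes 32 passed, 21 higher and 11 lower, against 19 and 20 with TMM, 19 and 22 with DESeq2 scaling, 18 and 21 with total counts, 18 and 16 with positive controls and 18 and 16 in the authors' normalised values. There was no overlap between groups for 32 of the 55 tested, where chance gives 1.67%, and 30 of these had passed.

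The differences from bone marrow were alike in both genotypes, with a Pearson r of 0.879 and a Spearman rho of 0.884 across 55 genes for control intestine, and 0.92 and 0.901 for inflamed intestine. In control intestine 14 genes were higher in both genotypes, where 5.3 would be shared by chance, and 2 lower, where 0.1 would be. In inflamed intestine the counts were 18, against 7.6 by chance, and 7, against 1.4.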

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

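The tests of explanations in this part, what each would predict (the splits of the samples included) and the multiplier classes were set down only after the results were seen, whereas the interaction test and the search for samples far from their group were planned.

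Il10 rose more, and Cd80 less, in Trem1-/- than in WT cells of the inflamed intestine, with interactions of 1.74 and -1.48 on the log2 scale. A constant offset between the samples of the 2 genotypes cancels in an interaction and so cannot give the values of 1.741 (SE 0.395) and -1.479 (SE 0.378). With the multiplier class as a block the interactions stayed at 1.675 (SE 0.418, adjusted p = 0.0407) and -1.384 (SE 0.384, adjusted p = 0.0448). The 4/3 class held 2 samples of each control group, 2 of WT inflamed and 3 of Trem1-/- inflamed. A class difference common to all groups would thus nearly cancel in the interaction. The block could hardly have removed these values, so no conclusion is drawn from it. In the intestine the 4/3 class merged 1.333 (WT) with 1.33 (Trem1-/-), so a difference between these was not tested. Over the alternatives the interaction ranged from 1.41 to 2.04 for Il10 and from -1.78 to -0.91 for Cd80, and 5 of 100 splits of the samples called as many genes as the real groups, so chance is not excluded for the count of 2. A biological hypothesis, that donor cells without Trem1 respond with more Il10 and less Cd80, stays open beside chance and an unrecorded run effect.

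The 13 genes lower in Trem1-/- than in WT cells of the inflamed intestine had a median log2 fold change of -1.28. With the multiplier class as a block, 11 of the 13 stayed lower, at a median of -1.16 (SD 0.96). WT inflamed cells had 2 samples deposited unscaled, 2 multiplied by about 4/3 and 1 multiplied by 2. Trem1-/- inflamed cells had 4, 3 and 0. With classes so nearly balanced, the block could hardly have removed a genotype difference, so no conclusion is drawn from it. The 4/3 class also merged slightly different multipliers of WT and Trem1-/- intestinal samples, so a difference between these was not tested. With TMM scaling 2 of the 13 stayed past the threshold, at a median of -0.66 (SD 1.00). TMM, which centres the panel, moved the median of all genes by 0.54. The panel itself thus cannot tell a shared fall from a shift of the 3 housekeeping genes. These did not move alike: before scaling, Gapdh counts were 51728 to 95817 in WT and 102831 to 129929 in Trem1-/- inflamed samples. Those of Actb were 71677 to 128120 and 104027 to 128383. Leaving out 1 housekeeping gene moved the median of all genes by -0.083 to 0.141. The samples of the genotypes may also have been handled apart: in 10 of 10 WT intestinal samples the positive-control mean lay below that of every Trem1-/- intestinal sample (at most 729.3 against at least 766.2; log2 difference 0.93 in control intestine, exact permutation p = 0.0079, and 1.22 in inflamed intestine, exact permutation p = 0.0013), so genotype and run cannot be told apart. Differences between genotypes in control and in inflamed intestine had r = 0.401 across 55 genes, which leaves an offset shared by both states open as well.

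Ly6c1 and Tlr4 stood out among these 13 genes because their direction turned among samples multiplied by about 4/3. WT inflamed mice 3 and 4, of that class, did not share the levels of the other WT inflamed mice. Among samples deposited unscaled the log2 fold changes between genotypes were -7.01 (SE 1.06, adjusted p = 0.000768) and -1.99 (SE 0.32, adjusted p = 0.000768), and among those multiplied by about 4/3 they were 0.585 (SE 0.699, adjusted p = 0.595) and 0.15 (SE 0.282, adjusted p = 0.727). WT inflamed mouse 5, multiplied by 2 and in neither fit, lay near the unscaled mice, at log2 levels of 15.02 and 15.09. With group held fixed, unscaled and 4/3 samples of the intestine differed by 0.34 for Ly6c1 (adjusted p = 0.831) and 0.19 for Tlr4 (adjusted p = 0.542). Such a pooled value cannot show a class difference that varies between groups. For Ly6c1, 4/3 samples lay below the unscaled ones in WT inflamed cells (9.53 and 9.70 against 15.82 and 13.64). In Trem1-/- inflamed cells they lay mostly above (8.67, 10.77 and 10.42 against 9.05, 7.35, 7.56 and 7.79). Mice 3 and 4 were also the lowest WT inflamed mice for Spi1 (15.60 and 15.51 against 16.44, 16.58 and 16.20). The same held for Traf6 (14.26 and 13.80 against 15.04, 15.71 and 15.04). For Spi1 both stayed above every Trem1-/- inflamed sample (at most 14.99), while for Traf6 mouse 4 did not (at most 14.15). With 2 mice, an effect of the 4/3 class cannot be told from a difference of mice 3 and 4 themselves, and a loss of Ly6c1 that depends on Trem1 stays a hypothesis.

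For inflamed against control intestine, 1 of 100 splits of the WT samples, the real one, called as many as 26 genes, and the highest other called 7. In Trem1-/- cells it was 1 of 100 for 27 genes, with 7 for the highest other, and between genotypes in inflamed intestine 1 of 100 for 18 genes, with 8 for the highest other. Of 126, 792 and 792 possible splits 100 each were drawn, so chance is unlikely for these 3 counts but not excluded. A run effect that follows genotype is not addressed by these splits. Between genotypes in control intestine 5 of 100 splits called at least the real 2 genes. The highest other called 19, several times the real count, and the median of the others was 0. What set the split with 19 calls apart was not tested. Chance is not excluded there, nor for the interaction, where 5 of 100 splits called at least 2 genes and the highest other called 5.

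In bone marrow, 10 splits are too few for a share under 0.05. The real split called 0 genes and the highest other 6. The split with 6 calls separated the WT and Trem1-/- samples of the same number in 1 of 3 pairs. Every split that separated all 3 pairs, the real one among them, called 0. For intestine against bone marrow, only the real split called as many genes in each case. It was 1 of 56 splits for WT control (19 genes, highest other 13) and 1 of 56 for WT inflamed (27, highest other 9). It was 1 of 56 for Trem1-/- control (19, highest other 11) and 1 of 100 for Trem1-/- inflamed (32, highest other 3). Chance is therefore unlikely for these counts.

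Single samples lay far from their group, by the gap to the nearest other sample, in 11 of 152 gene and group pairs, where chance gives about 7.6. Values are log2 normalised counts, beside the mean of the other samples. WT control mouse 5 had 8.79 for Ccl7 (others 6.48), 5.41 for Il6 (6.2) and 11.07 for Irf4 (12.53). WT inflamed mouse 2 had 17.35 for Cd14 (16.76), 12.26 for Csf1r (14.26) and 5.46 for Tlr2 (7.28). Trem1-/- control mouse 2 had 13.94 for Cd80 (13.39). Trem1-/- inflamed mouse 5 had 14.51 for Il10 (15.50), mouse 7 had 10.60 for Cxcl9 (6.77) and mouse 1 had 5.43 for Tlr2 (6.16). WT control mouse 4 had 12.85 for Retnla (5.63), a target deposited only for WT intestinal samples. The edgeR call of Retnla between inflamed and control cells (log2 fold change -4.37, adjusted p = 0.0491) rested on that mouse, and the exact permutation test gave p = 0.976.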

How the results depend on the processing

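Blocks by multiplier class, fits within a class and counts as deposited were chosen after the data were seen, and the other alternatives were planned except the blocks of the list tests. Of the pairs of a gene and an alternative, for the 157 of 172 called genes that were named, 4498 kept direction and call, 416 lost the call and 15 turned direction. All alternatives were kept by 12 of 25 named genes for inflammation in WT cells, 11 of 25 in Trem1-/- cells, 1 of 18 (Cd80) between genotypes in inflamed intestine, 0 of 2 in control intestine and 0 of 2 for the interaction. Against bone marrow it was 5 of 19 (WT control), 16 of 21 (WT inflamed), 6 of 19 (Trem1-/- control) and 22 of 26 (Trem1-/- inflamed). The counts as deposited gave the same counts of calls, which is no test of the multipliers, since these also apply to the housekeeping genes and cancel in the scaling. The cause of the changes below was not tested, except that scaling moves all genes together: between genotypes in inflamed intestine the median moved by 0.54 with TMM, 0.42 with DESeq2 scaling and -0.93 with positive controls. Pre-amplification hides how many molecules lie behind a count, and values near the background limit (median 41.7) carry little signal.

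Genotype in control intestine (2 genes) gave 0 with TMM, DESeq2 or total-count scaling, 29 with positive controls, 4 without Rpl19, 11 with the DESeq2 test, 12 in the authors' values, 1 with the mouse block, 6 with the class block, 11 in unscaled samples and 13 in those multiplied by about 4/3 (multiplied samples below). Without a mouse it gave 1 (WT 2 or 3, Trem1-/- 2, 3 or 4) to 6 (WT 5, Trem1-/- 5). The interaction (2) gave 0 with DESeq2 scaling, in the authors' values and in multiplied samples, 1 with positive controls or the mouse block, 4 with the DESeq2 test or class block and 16 in unscaled samples. Without a mouse it gave 1 (WT control 2, WT inflamed 2 or 5, Trem1-/- control 2) to 4 (Trem1-/- inflamed 5). Bone marrow (0) gave 2 with positive controls or the DESeq2 test, 1 without Rpl19 or with all 6 groups, and 0 to 2 without a mouse (2 without WT 1, 1 without WT 3 or Trem1-/- 1). WT control against bone marrow (19) gave 11 with positive controls or the mouse block, 8 in the authors' values or with only these groups, 12 in unscaled samples and 12 to 24 without a mouse (12 without WT bone marrow 1 or 3). Trem1-/- control against bone marrow (19) gave 12 in unscaled samples. Genotype in inflamed intestine (18) gave 9 with TMM and 29 with positive controls. Inflammation in WT cells (26) gave 17 with positive controls. List tests past the threshold numbered 53, and 35 with positive controls (25 lost, 7 gained). Trem1 in WT cells ran from 1.795 to 2.759 without a mouse.

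Directions turned as follows on the log2 scale. Genes that had not passed (here Arg1, Tnf, Mrc1, Cxcl10 and, in Trem1-/- inflammation, Cd80) were picked for this by hand after the results were seen. They made 14 pairs of a gene and a comparison in all. In multiplied samples Tlr4 gave -0.175 (WT inflammation) and 0.15 (genotype, inflamed), Ly6c1 0.585, Arg1 -0.571 (genotype, inflamed) and Cxcl10 -0.714 (interaction). The interactions of Mrc1 (1.42, adjusted p = 0.504) and Arg1 (3.00, adjusted p = 0.187) gave -0.344 and -0.82 in multiplied samples and 3.57 and 6.75 in unscaled ones, the 1 alternative of 43 in which each passed, and Arg1 gave 1.26 without WT control mouse 5. Tnf (genotype, inflamed) gave -0.256 in multiplied samples, with a range up to 1.09 and 0 of 34 alternatives past the threshold. For genotype in inflamed intestine, positive controls gave Arg1 -0.316 and Tnf -0.328, and unscaled samples Arg1 3.55. In the authors' values for Trem1-/- inflammation Card9 gave 0.081, Irf4 0.028, Spi1 0.198 and Nfkb1 0.159. Cd80 there gave -0.177 with TMM, -0.306 with total counts and -0.034 without Actb. Against WT bone marrow, Tgfb1 in control cells gave -0.057 with TMM, -0.324 with DESeq2 scaling and -0.096 in the authors' values, and H2-Ab1 in inflamed cells gave -0.945 in unscaled samples. Against Trem1-/- bone marrow, the authors' values gave Ccl2 -0.175, Il10 -0.203 and Tgfb1 -0.976 in control cells, the last past the threshold in the opposite direction (adjusted p = 0.0491), and positive controls gave Tgfb1 -0.352.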

Other observations

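The values in this part were chosen after the data were seen. In the WT inflamed group, the samples multiplied by about 4/3 (mice 3 and 4) had log2 normalised counts of 9.53 and 9.70 for Ly6c1, a marker of classical monocytes, where mice 1 and 2 (unscaled) and 5 (multiplied by 2) had 15.82, 13.64 and 15.02. For Arg1 mice 3 and 4 had 17.94 and 17.22, and the others 14.004, 12.8 and 12.5. For Siglec1, a sialic acid receptor of macrophages, mice 3 and 4 had 11.78 and 12.999, and the others 6.19, 6.69 and 6.01. For Mrc1 they had 9.43 and 9.53, and the others 6.50, 6.42 and 6.15. The 7 Trem1-/- inflamed samples averaged 8.80 for Ly6c1 and 10.74 for Mrc1.

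With group held fixed, 15 of 55 genes differed between samples deposited unscaled and those multiplied by about 4/3 across the intestine. Of 14 macrophage maturation genes, 7 were lower in unscaled samples, 1 was higher (Spi1, at 0.41) and 6 did not pass, with no test of the list. Among the 7 were Adgre1 (F4/80) at -1.77 (adjusted p = 0.00079), Cd68 at -1.59 (adjusted p = 0.000634) and Trem2 at -1.22 (adjusted p = 0.0087) on the log2 scale. The lower levels were not particular to this list: of 8 chemokine receptors and adhesion genes, 4 were lower in unscaled samples and 4 did not pass. Of the 15 genes, only Spi1 and Traf6 were higher, Traf6 at 0.73 (adjusted p = 0.00276). Residuals of 83 pairs of samples of the same class had a mean r of 0.083, and those of 97 pairs of different classes of -0.07.

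Fcgr1 and Cd68 did not differ past the threshold between inflamed and control intestine in either genotype. Fcgr1, the high-affinity receptor for immunoglobulin G, had 36646 ± 14464 (control) and 30596 ± 12464 (inflamed) normalised counts in WT cells (SD, n = 5 each), and 28387 ± 10690 (n = 5) and 35629 ± 7948 (n = 7) in Trem1-/- cells. Cd68, a lysosomal marker, had 12660 ± 5817 and 10176 ± 6840 in WT cells, and 9878 ± 8436 and 11524 ± 6538 in Trem1-/- cells.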
